A study of Mus musculus with 22 samples.

How the data were processed

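Hippocampus and frontal cortex of 11 mice were profiled by OMNI-ATAC-seq from 20 to 30 mg of frozen tissue with paired-end reads of 50 bp, per the labels' protocols. 1 further baseline animal was excluded for low read depth, per the series' design text. The submitters' processing notes name Trim Galore 0.6.7, FastQC 0.11.9, Bowtie2 2.4.4 and MACS2 2.2.7.1 and the GRCm38 (mm10) build. Whether reads were shifted for the transposase is not given in the sources used here. Peaks were deposited per library, so libraries are the replicates, and each comes from a separate animal within its tissue. For every peak the authors deposited a score, a fold ratio over background, and -log10 p and -log10 q values, which were used only to rank or filter peaks within a library. The lowest deposited -log10 p lay just above 2 in every library, so the peaks passed an unadjusted threshold near 0.01. The lowest -log10 q per library lay between 0.501 and 0.643, so the lists hold weak peaks. The 6 differential tables deposited by the authors hold regions with a direction and a number read here as -10 times log10 of the FDR, since its lowest value then gives a highest FDR of 0.05. They hold no fold changes, and their starts were read as 1-based, since all widths are then multiples of 10 bp. Peak lists carry no read depth, so no interval or detection limit that needs depth is given.

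Distinct peak intervals were counted once where several summits shared 1 interval. Consensus windows of 501 bp were placed around summits, kept greedily by the peak's score relative to its library's total, without overlap, which gave 563530 windows. A window was present in a library where a peak overlapped it by at least 50% of the shorter. Windows present in 2 to 20 libraries were compared between tissues by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. The animal pairs the tissues, as the labels give the same animal for both, and an exact sign test over animals was the paired alternative. Differential regions were set against windows present in 2 or more libraries of the tissue (354278 in hippocampus, 328190 in frontal cortex). Odds ratios have Woolf 95% intervals. Counts of windows that switch between saline and LPS were set against all other splits of the libraries.

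The gene table used is of the same build but gives no strand, and no genome sequence was used. Windows were therefore assigned to the nearest protein-coding gene body within 100 kb in place of the nearest transcription start, and the promoter test became a test for either end of a gene within 1 kb. Motifs were not tested and a fold change threshold was not applied. These departures from the planned tests were settled after the data were seen. The 16 lists held 383 distinct genes, and 1 further symbol had no match. Genes were named by a rule set before the data were examined: per comparison up to 10 regions per direction with the lowest FDR, ties by width and position, plus up to 10 regions of list genes, and between tissues the 10 genes with the largest net number of windows per direction plus 2 to 4 genes per list. A selection of those is printed, and some named by the rule are not reported here. Rorb, Prox1 and Nr3c2 come from the lists. A further list of striatal neuron markers was written after the data were seen, as was the comparison of the deposited gene labels with the gene table.

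Alternatives covered stricter peaks (-log10 q of 5 or more), equal numbers of peaks per library (50000), the overlap required, gene assignment, background, an FDR of 0.01, and leaving out each library or animal. Group differences of single values were tested by exact permutation. For LPS against saline the two-sided p was the smaller one-sided p doubled, which sets its lowest possible value. The shared saline libraries were simulated with 10 draws of unchanged groups, as normal values per window for 3 libraries against the same 2. After the data were seen, the same draws were set beside overlaps across tissues at different times, which share the saline animals but not the libraries. The tests were tested on simulated data first. In the tissue comparison, with 98218 of 327394 simulated windows changed (a peak chance of 90% in 1 tissue and 10% in the other) the tissue test recovered 94.1%, and with 2000 changed it recovered 33.3%, where exact binomial power was 33.9%. In the list enrichment test a planted odds ratio of 3.09 came out as 2.65, and 5% of random lists had an unadjusted Fisher's exact p under 0.05. These simulated lists were single windows drawn independently. They do not give the error rate for real lists, whose genes hold several related windows. Of windows that switch, 300 gained and 100 lost were planted, and 310 and 108 were found. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.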

Results

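Open chromatin was profiled in hippocampus and frontal cortex of adult male C57BL/6J mice in a model of Gulf War Illness. The animals drank corticosterone, the rodent stress glucocorticoid, for 7 days, received diisopropyl fluorophosphate, an organophosphate inhibitor of acetylcholinesterase, on day 8, and had intermittent corticosterone over 5 weeks. They were then given saline or lipopolysaccharide (LPS), a bacterial cell wall component that triggers systemic inflammation. OMNI-ATAC-seq, in which a transposase inserts adapters into accessible DNA, gave 22 libraries from 11 animals, 1 library per tissue and animal. Each tissue had 2 saline libraries (collected at 6 h, replicates 2 and 3) and 3 LPS libraries at each of 6, 12 and 24 h (replicates 1, 3 and 4). Read depth per library is unknown from peak lists. The libraries held 204599 to 307186 distinct peak intervals, which covered 81.0 to 113 Mb. The hippocampus libraries held 262158 ± 21630 intervals (SD, n = 11) and the frontal cortex libraries 242051 ± 22842 (SD, n = 11), with more in hippocampus in 9 of 11 animals (exact sign-flip permutation test, two-sided p = 0.0410, adjusted p = 0.205 over 15 library tests, and an unadjusted exact p from 0.0508 to 0.0820 when any 1 of 9 of the animals was left out). Between LPS and saline no difference in this number passed the test (exact permutation test, two-sided p = 0.291 in hippocampus and 0.945 in frontal cortex, where 55 splits allow no p below 0.0364). Within 1 kb of a gene end lay 7.80% ± 0.352 of the intervals in hippocampus and 8.36% ± 0.517 in frontal cortex (SD, n = 11 each, exact sign-flip p = 0.00586, adjusted p = 0.0879).

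The first comparison asked where hippocampus and frontal cortex differed in accessibility, over all challenge groups. Zbtb20, a transcription factor gene of hippocampal pyramidal and granule neurons, had 62 windows more often present in hippocampus and 4 more often present in frontal cortex (chromosome 16, 42875689 to 43634392, GRCm38). Prox1, a regulator of dentate granule cells, had 19 and 1, and Nr3c2, the mineralocorticoid receptor gene, had 29 and 7. On the cortical side, Rorb, a layer 4 marker, had 3 windows more often present in hippocampus and 18 in frontal cortex. In total 99757 of 327394 tested windows were called, 59877 towards hippocampus and 39880 towards frontal cortex (Fisher's exact test, 11 libraries against 11, Benjamini-Hochberg adjusted p under 0.05). A peak in all 11 hippocampus libraries and no cortex library was seen at 13816 windows, and the converse at 7662. With animals as the replicate block, 41780 and 26637 windows were called. With peaks of -log10 q of 5 or more, 74907 windows were called, of which 51681 were also called with all peaks in the same direction. With the 50000 strongest peaks of each library the direction of the balance turned, with 14784 windows towards hippocampus and 15119 towards frontal cortex.

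The genes with the largest net number of windows towards hippocampus were Lsamp (90 against 26), Zbtb20, Tenm3 (75 against 21), Auts2 (63 against 11), Pard3 (48 against 5), Tenm2 (64 against 21), Thsd7b (48 against 5), Macrod2 (81 against 39), Shisa6 (47 against 5) and Ryr3 (42 against 2). Those towards frontal cortex were Dpp10 (20 windows towards hippocampus, 49 towards cortex), Ntm (35 and 63), Fhod3 (7 and 34), Syt1 (14 and 40), Pcdh7 (11 and 36), Ptprd (65 and 90), Rora (19 and 44), Kcnh7 (15 and 38), Hecw2 (6 and 28) and Tmem132d (15 and 36). These are long genes: Lsamp, which encodes a neuronal adhesion protein, spans 2197 kb. Ryr3 encodes an intracellular calcium channel and Syt1 the calcium sensor of synaptic vesicle release. With the 50000 strongest peaks the net count of Ntm and of Hecw2 turned towards hippocampus, and that of Auts2 and of Syt1 was 0.

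Gene lists fixed before the data were examined differed in the direction of their called windows. Hippocampal region markers leaned towards hippocampus, with 265 windows against 116 (odds ratio 1.52, 95% interval 1.22 to 1.90, Fisher's exact test, two-sided adjusted p = 0.000503 over 16 lists), and Zbtb20 held 62 of the 265. Inhibitory neuron markers did so with 110 against 45 (odds ratio 1.63, Fisher's exact test, adjusted p = 0.0138), among them Adarb2 (24 and 4) and Prox1 (19 and 1), which is also in the hippocampal list, and endothelial and mural cell markers with 55 against 19 (odds ratio 1.93, adjusted p = 0.0247), among them Kdr (12 and 2). Circadian clock genes leaned towards frontal cortex, with 65 windows against 110 (odds ratio 0.393, Fisher's exact test, adjusted p = 2.25e-08), of which Rora held 19 and 44 and Rorb, also a cortical layer marker, 3 and 18. Against the 60.02% hippocampal share of all called windows, 4 further lists lay towards frontal cortex. Cortical layer markers had 205 against 213 (odds ratio 0.640, Fisher's exact test, adjusted p = 4.95e-05) and synaptic genes 395 against 361 (odds ratio 0.727, adjusted p = 7.93e-05). Excitatory neuron markers had 152 against 150 (odds ratio 0.674, Fisher's exact test, adjusted p = 0.00247) and cholinergic and esterase genes, which include targets of organophosphates, 56 against 61 (odds ratio 0.611, adjusted p = 0.0185).

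The other 8 lists did not pass: acute inflammatory and NF-kB response (64 against 39), interferon response (14 against 4), glucocorticoid response and stress axis (74 against 50), immediate early and activity genes (66 against 45), microglia (38 against 21), astrocyte (57 against 31), oligodendrocyte lineage (31 against 23), and blood leukocyte and erythroid markers (10 against 1). Adjusted over the list alone, the counts were 12 and 4 for interferon response, 31 and 17 for microglia and 27 and 21 for oligodendrocyte lineage markers, and equal to those above for the other 13 lists. Windows of 1 gene are not independent, and single genes carried much of each lean. Without the 2 genes that leaned furthest in the direction of a list, a choice made after the data were seen that can only weaken a lean, none of the 8 lists passed (Fisher's exact test, adjusted p from 0.1103 to 0.963). The odds ratio was then 1.11 for hippocampal region markers without Zbtb20 and Nr3c2, 1.12 for inhibitory neuron markers without Adarb2 and Prox1 (67 windows against 40), and 1.41 for endothelial markers without Kdr and Tbx18. It was 0.596 for clock genes without Rora and Rorb (43 against 48), 0.808 for excitatory neuron markers without Rbfox3 and Mef2c, 0.845 for synaptic genes without Syt1 and Dlg2, 0.975 for cholinergic genes without Chrm2 and Chrm3, and 0.762 for cortical layer markers. None of the 8 calls was kept with the 50000 strongest peaks (Fisher's exact test, adjusted p from 0.176 to 0.212), where fewer windows were called and each odds ratio stayed on its side of 1. They were 1.38 for hippocampal region, 1.72 for inhibitory neuron and 2.43 for endothelial markers, 0.511 for clock genes, 0.756 for cortical layer markers and for synaptic genes, 0.691 for excitatory neuron markers and 0.584 for cholinergic genes. The endothelial and cholinergic calls were also lost with genes taken within 10 kb (Fisher's exact test, adjusted p = 0.547 and 0.0755).

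**Figure D1:**
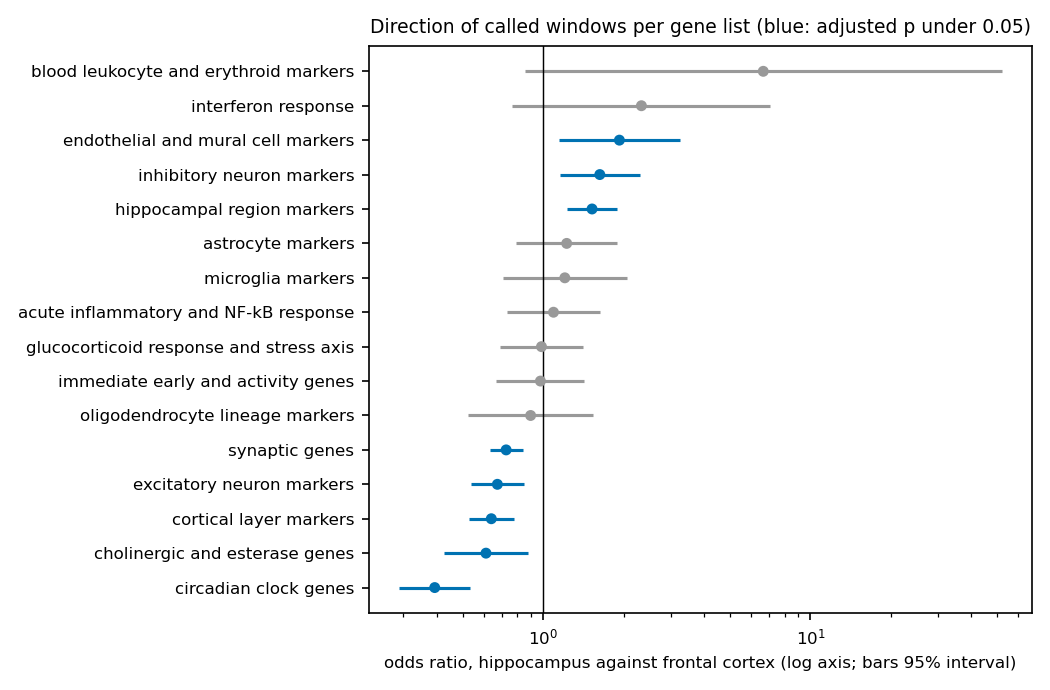
Odds ratio, on a log axis, of windows called towards hippocampus against frontal cortex for each of 16 gene lists, with 95% intervals as bars and lists whose adjusted p is under 0.05 in blue. Circadian clock genes lie lowest at 0.393, and the interval of hippocampal region markers, 1.22 to 1.90, lies above 1.

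The second comparison, made by the authors with csaw within each tissue, asked which regions differed 6, 12 and 24 h after LPS from saline. All saline libraries were collected at 6 h, so at 12 and 24 h LPS and collection time cannot be told apart. In hippocampus the authors' deposited table listed 23 regions at 6 h, 3084 at 12 h and 179 at 24 h. At 12 h the authors' deposited table had 1211 regions higher and 1873 lower in LPS, and at 24 h 97 higher and 82 lower. At 6 h it was 2 higher and 21 lower in the authors' deposited table. The authors' deposited table gives no fold changes, so regions are described by direction and FDR. The region with the lowest FDR among those higher at 12 h lay 18869 bp from Bet1 (chromosome 6, 4057951 to 4058110, GRCm38; FDR 1.92e-05 in the authors' deposited table), and it was listed again at 24 h. Others higher at 12 h, per the authors' deposited table, lay 47348 bp from Cbln1, a synaptic organiser gene (FDR 0.000154), in an intron of Ccser1 (FDR 0.000559) and in an intron of Pde3a, a cyclic nucleotide phosphodiesterase gene (FDR 0.00083). At 24 h the authors' deposited table listed higher regions in introns of Elmo1, an engulfment gene, and Pik3cg, a leukocyte kinase gene (both FDR 0.00863), and 4872 bp from Kdr, the endothelial VEGF receptor gene (FDR 0.0309).

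Regions lower in hippocampus included an exon of Sh2b2, an adaptor of receptor tyrosine kinases (chromosome 5, 136224401 to 136224960), with an FDR of 2.34e-08 at 12 h in the authors' deposited table. The authors' deposited table listed this Sh2b2 region as lower in all 6 comparisons. All 6 use the same 2 saline animals, so they are not separate replications. In hippocampus this region had a peak in 3 LPS libraries at each time and in 2 saline libraries. An exon of Ush1c was lower at 6, 12 and 24 h, with an FDR of 0.000111 at 12 h in the authors' deposited table. Among genes of the fixed lists, the authors' deposited table had lower regions at 12 h at 34548 bp from Kcnk2 (FDR 9.31e-05), 9874 bp from Pdgfra (FDR 0.00301) and 59182 bp from Nptx2 (FDR 0.00449), and in introns of Rorb (FDR 0.00451) and Rora (FDR 0.00757). A region in an intron of Meis2 was higher (FDR 0.00591 in the authors' deposited table).

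The deposited peaks showed which libraries carried these differences. Regions higher in hippocampus at 12 h had a peak in 88.8% ± 5.25 of cases in the 12 h libraries (SD, n = 3) and in 48.0% ± 1.87 in saline (SD, n = 2). The same share was 83.3, 72.3 and 77.6% in the 24 h libraries and 58.4, 62.3 and 72.9% in the 6 h libraries. Regions lower at 12 h had a peak in 63.3% ± 20.7 of cases in the 12 h libraries (SD, n = 3) and in 94.1% ± 5.96 in saline (SD, n = 2), with 86.0% in 12 h replicate 3 against 45.5% in replicate 1. These regions were chosen on the same libraries, so the shares are no independent evidence. With 3 libraries against 2, an exact two-sided permutation p, doubled from the one-sided p, cannot fall below 0.2. Windows at the regions higher at 12 h lay within 1 kb of a gene end in 1.64% of cases, against 8.45% of the other hippocampal windows (odds ratio 0.180, Fisher's exact test, two-sided adjusted p = 9.47e-23 over 10 sets), and windows at the lower ones in 3.10% (odds ratio 0.347, adjusted p = 2.51e-20). For regions higher at 24 h it was 2.11% (odds ratio 0.234, Fisher's exact adjusted p = 0.0346), which did not pass at 5 kb (odds ratio 0.560, adjusted p = 0.0962) or against windows present in every library (odds ratio 0.507, adjusted p = 0.640). For regions higher and lower at 12 h the odds ratios were 0.294 and 0.617 at 5 kb, and for the lower ones 0.210 against windows present in every library. The units of these and all later gene end tests are windows, so their p does not measure the spread between animals or the strength of an LPS effect. With the 50000 strongest peaks the difference in the share with a peak was 10.96 percentage points for regions higher at 12 h, against 40.8 with all peaks, and 10.1 against 43.6 for those at 24 h. Libraries of the other tissue were not used to choose the regions. They come from the same animals, including the 2 saline animals, so they are not independent evidence either. Over 12 region sets the exact permutation tests there gave two-sided adjusted p from 0.291 to 1, but 55 splits allow a set to pass only where at least 9 of the 12 have the smallest possible p, so these adjusted values decide little. In frontal cortex libraries, regions higher in hippocampus at 12 h had a peak in 58.6% ± 7.53 of cases over the LPS libraries (SD, n = 9) and in 47.2% in saline (exact permutation p = 0.0727), and those higher at 24 h in 61.7% ± 8.09 (SD, n = 9) and 46.4% (exact permutation p = 0.0364, the smallest that 55 splits allow). These 2 sets overlap: of the 99 windows at regions higher in hippocampus at 24 h, 76 were also at regions higher at 12 h. In hippocampus libraries, regions higher in frontal cortex at 24 h had a peak in 65.5% ± 4.36 of cases (SD, n = 9) and in 61.9% in saline (exact permutation p = 0.364).

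**Figure D2:**
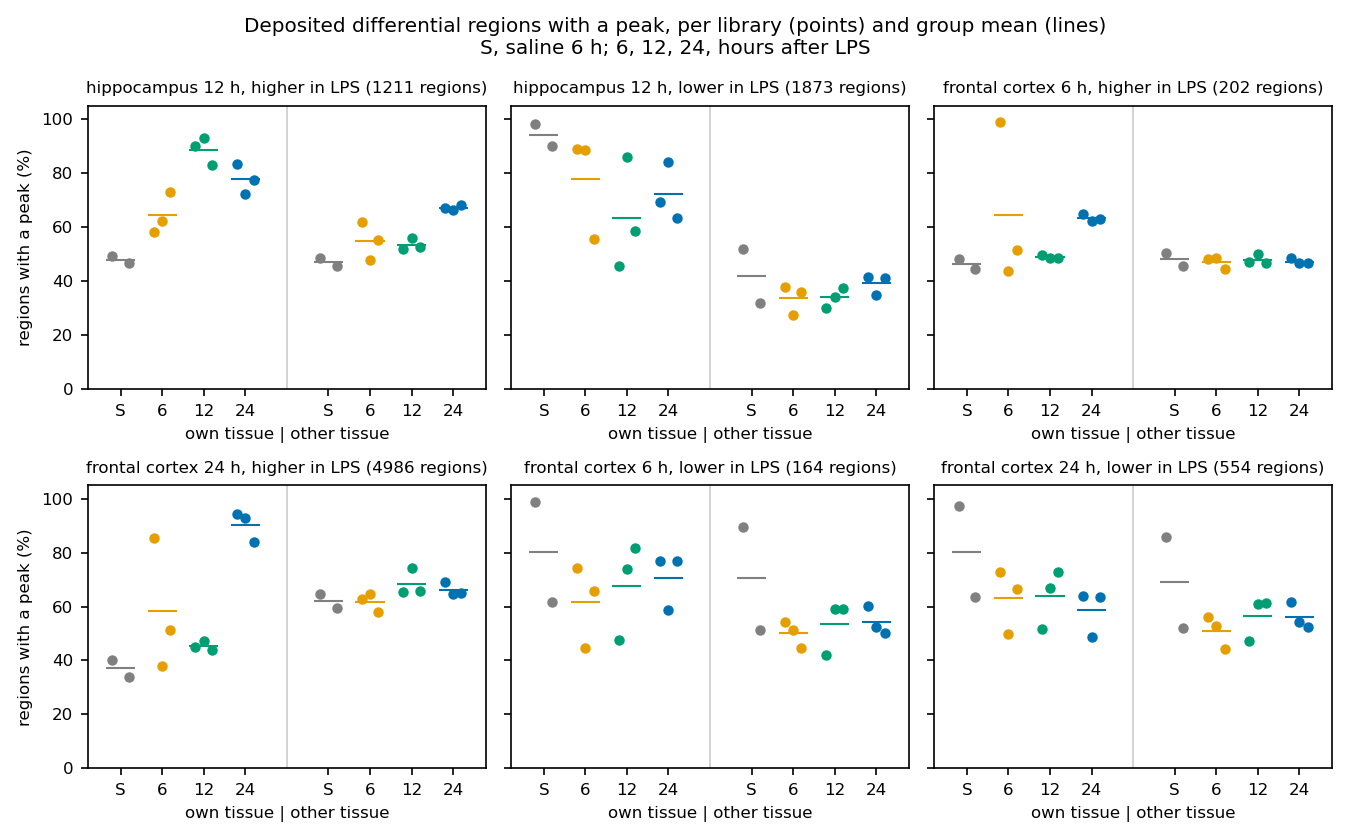
Share of deposited differential regions, in percent, that a library's peaks overlap, with 1 point per library, lines for group means, the tissue of the comparison on the left of each panel and the other tissue on the right. For regions higher in frontal cortex at 6 h, 1 library lies at 99.0%, and for regions lower in frontal cortex 1 saline animal lies above the other in both tissues.

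In frontal cortex the authors' deposited table listed 366 regions at 6 h, 52 at 12 h and 5540 at 24 h. At 24 h the authors' deposited table had 4986 regions higher and 554 lower, so 90% were higher. The authors' deposited table placed 2184 of the higher regions in introns, 264 at promoters, 145 in exons and 2393 outside genes. Of the 2184 intron labels, 111 named a gene whose body in the gene table lay over 5 kb away, 40 of them Mir3084-2, so a label does not always place a region in the gene it names. Named regions included an intron of Adamtsl1 (FDR 5.34e-14 in the authors' deposited table) and a site 60640 bp from Penk, the proenkephalin gene (chromosome 4, 4199401 to 4199510; FDR 5.34e-14 in the authors' deposited table). Fixed-list genes with a higher intronic region in the authors' deposited table were Meis2 (FDR 1.72e-09), Syt6 (FDR 6.56e-09), Gad2, a GABA synthesis gene (FDR 8.79e-09), Gja1, an astrocyte gap junction gene (FDR 1.53e-07), and Dlg2 (FDR 3.14e-07). Others in the authors' deposited table lay outside genes, at 65264 bp from Egr2 (FDR 5.74e-11), 7942 bp from Tlr2, a receptor for bacterial lipoproteins (FDR 2.83e-10), 85211 bp from Arpp21 (FDR 9.70e-09) and 91108 bp from Jun (FDR 1.36e-07). Regions lower at 24 h lay 8425 bp from Nsun2 (FDR 1.21e-08) and in introns of Acsbg2 (FDR 1.82e-06), Babam2 (FDR 6.82e-06), Ank3 (FDR 1.38e-05) and Usp34 (FDR 1.61e-05), all in the authors' deposited table. Those at Nsun2, Acsbg2 and Usp34 had a peak in 0 LPS libraries at 24 h and in 1 saline library, and that at Babam2 in 0 and 2. The Ank3 region had a peak in 3 LPS and 2 saline libraries.

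The regions higher in cortex at 24 h had a peak in 94.2, 92.7 and 83.8% of cases in the 3 libraries at 24 h and in 40.3 and 33.9% in saline. Replicate 1 at 6 h also had a peak in 85.3% of cases, against 37.8 and 51.4% in the other 6 h libraries. The difference from saline at 24 h was 53.2 percentage points, and 8.83 with the 50000 strongest peaks. Windows at these regions lay within 1 kb of a gene end in 1.70% of cases, against 9.08% of the other cortical windows (odds ratio 0.173, Fisher's exact test, two-sided adjusted p = 6.10e-102), with odds ratios of 0.310 at 5 kb and 0.103 against windows present in every library. This p too is over windows of 1 comparison of 3 libraries against 2, not over animals.

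At 6 h the frontal cortex differences had another make-up. The authors' deposited table gave 202 higher and 164 lower regions, and its lowest FDR, 6.15e-51, stood at chromosome 1, 24613101 to 24614610, 25933 bp from Col19a1. The regions with the next lowest FDRs, at 24614651 to 24616160 and 24611551 to 24613060, lay on either side of it. Other leading regions in the authors' deposited table lay 19182 bp from Mid1 on chromosome X (FDR 8.95e-33), in an intron of Myo3a (FDR 8.17e-32) and at the promoter of Gm3435 (FDR 1.03e-29). A region on chromosome Y, 90784801 to 90785060, had the same FDR as that near Mid1. Each of these regions had a peak in 1 LPS library at 6 h and in 0 saline libraries. Replicate 1 had a peak at 99.0% of the 202 regions, against 43.6 and 51.5% in replicates 3 and 4 and 48.0 and 44.6% in saline, and 106 regions had a peak in at least 2 of the 3 LPS libraries. As replicate 1 had nearly all, the 106 mostly count regions with a peak in replicate 3 or 4, whose shares were near those in saline. The share in LPS exceeded that in saline by 18.4 percentage points, by 1.24 without replicate 1 and by 29.0 without replicate 3. Of the windows at these regions 27.3% lay within 1 kb of a gene end, against 8.96% of the others (odds ratio 3.82, Fisher's exact test, adjusted p = 3.33e-11), and for regions lower at 6 h it was 1.91% (odds ratio 0.198, adjusted p = 0.00106). The latter did not pass against windows present in every library (odds ratio 0.252, Fisher's exact test, adjusted p = 0.0704), and its odds ratio was 0.426 at 5 kb. Regions lower at 6 h in the authors' deposited table included a site 8425 bp from Nsun2 (FDR 3.02e-07) and the promoter of Plin4, a lipid droplet gene in the glucocorticoid list (FDR 0.0135). At 12 h the authors' deposited table had 7 higher regions, led by an intron of Itpr2 (FDR 0.00142), and 45 lower. For the regions lower at 6 h, saline replicate 2 had a peak in 98.8% of cases and saline replicate 3 in 61.6%, while the LPS libraries at 6 h had 61.6% ± 15.4 (SD, n = 3). In the hippocampus of the same 2 saline animals the shares were 89.6 and 51.2%. The difference of LPS from saline in frontal cortex was -18.6 percentage points, 0 without saline replicate 2, -37.2 without saline replicate 3 and -10.1 without LPS replicate 3. For regions lower at 24 h it was -21.5, -4.57 without saline replicate 2 and -38.3 without saline replicate 3.

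Acute inflammatory genes had 7 windows among regions higher in cortex at 24 h, at Tlr2, Nfkbia, Nfkbiz, Ptgs2, Tlr4 and Vcam1, where 5.89 were expected (Fisher's exact test, two-sided p = 0.535). Interferon response genes had 0 in that set, where 1.68 were expected (Fisher's exact p = 0.421), and microglia markers had 2, at Irf8 and Mertk, where 3.99 were expected (p = 0.449). Inhibitory neuron markers had 17, among them windows at Dlx6, Adarb2, Slc32a1, Gad2, Erbb4 and Reln, against 7.29 expected (odds ratio 2.38, 95% interval 1.47 to 3.87, Fisher's exact p = 0.00196, adjusted p = 0.145). In the same regions striatal neuron markers, a list written after the data were seen that also marks GABAergic neurons, had 31 windows against 8.42 expected (odds ratio 3.86, Fisher's exact p = 1.06e-09). Among regions lower in cortex at 24 h, circadian clock genes had 5 windows, at Arntl, Cry2 and Rorb, against 0.937 expected (Fisher's exact test, adjusted p = 0.145), and endothelial and mural cell markers 3, at Cdh5, Cldn5 and Tek, against 0.385 (adjusted p = 0.283). As saline was collected at 6 h, collection time is not separated from LPS for these clock genes. Synaptic genes had 4 windows among regions lower in hippocampus at 12 h, against 14.99 expected (odds ratio 0.264, Fisher's exact test, adjusted p = 0.145). This last list passed when regions had to have a peak in 2 LPS or both saline libraries (odds ratio 0.142, Fisher's exact test, adjusted p = 0.0292). With the deposited regions none of 160 tests passed after Benjamini-Hochberg adjustment, and 8 had an unadjusted Fisher's exact p under 0.05.

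Regions that recurred between comparisons were then counted. Higher regions of hippocampus at 12 h (1229 windows) and 24 h (99 windows) shared 76, where independent lists gave 0.281 and 10 simulations of unchanged groups against the same saline libraries gave 26.6 on average and 32 at most. Lower regions of these times shared 73 windows (0.374 for independent lists, 30.1 simulated, 34 at most). In frontal cortex, lower regions at 6 and 24 h shared 104 windows (0.219 and 26.8), whereas higher regions shared 35 (1.96 and 73.3), fewer than simulated. The simulation drew the saline libraries alike, whereas saline replicate 2 stood apart from replicate 3 at the lower cortex regions. The 2 saline libraries cannot be split, so part or all of each excess may come from the shared controls. Across tissues, higher regions of hippocampus at 12 h and cortex at 24 h shared 88 windows, and lower regions of these 2 comparisons shared 46. Independent lists gave 14.5 and 2.48, but both comparisons use the same 2 saline animals. Simulated as if these animals' libraries had been the same in both tissues, unchanged groups gave 371 and 125 on average. The observed overlaps lay between these values, and part or all of the excess over independent lists may come from the shared animals. For regions lower in cortex at 24 h, saline replicate 2 had a peak in 97.1% of cases in cortex and 85.7% in hippocampus, against 63.4 and 52.2% in saline replicate 3.

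Windows that switched between saline and LPS were counted last. In hippocampus 494 windows had a peak in all 9 LPS libraries and neither saline library, and 10 of 55 splits of the libraries gave as many. In frontal cortex it was 696 windows, with 5 of 55 splits giving as many. With the 50000 strongest peaks the share of splits was 0.0182 in hippocampus (234 windows) and 0.0364 in frontal cortex (187 windows). With all peaks and 1 library left out, it ranged in frontal cortex from 0.0444 without 6 h replicate 3 (1169 windows) to 0.2 without either saline library (4571 windows without replicate 2 and 4022 without replicate 3), where 10 splits remained. Windows lost with LPS numbered 1334 in hippocampus (8 of 55 splits) and 832 in frontal cortex (16 of 55). At 24 h in frontal cortex 11424 windows were gained, the most of 10 splits, where the next gave 7128 and no share can fall below 0.1. Libraries of the same group had a mean Jaccard index of 0.727 in frontal cortex, against 0.709 for other pairs (permutation test, one-sided p = 0.0136, adjusted p = 0.068 over 5 relations). In hippocampus these values were 0.717 and 0.708 (permutation test, one-sided p = 0.0901). The libraries of an animal had an index of 0.524 across tissues, against 0.519 for other animals of its group (exact permutation test, one-sided p = 0.0741). With the 50000 strongest peaks the permutation p was 0.00694 for animals (adjusted 0.0174), 0.00684 for groups in frontal cortex (adjusted 0.0174) and 0.0379 for groups in hippocampus (adjusted 0.0632).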

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

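Among the alternatives given here, those chosen only after the result was seen were regions with a peak in at least 2 LPS or both saline libraries, leaving out the animal whose cortex library stood apart, assignment to gene ends within 10 kb, tests of gene ends in place of transcription starts, and list splits without 2 genes. Motif tests and a fold change threshold were not run, and nearest transcription starts were replaced. For the changes below the cause was not tested, except where the setting itself lowers the number of regions, peaks or libraries.

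At an FDR of 0.01 the authors' deposited table kept fewer regions: in hippocampus 1 higher and 5 lower at 6 h, 173 and 367 at 12 h, and 4 and 11 at 24 h, and in frontal cortex 72 lower at 6 h, 3 higher and 10 lower at 12 h, and 2471 and 212 at 24 h. Overlaps fell with it: higher regions of hippocampus at 12 and 24 h to 3, hippocampus at 12 h and cortex at 6 h to 1, hippocampus at 12 h and cortex at 24 h to 7, hippocampus and cortex at 24 h to 1, and cortex at 6 and 24 h to 9. For lower regions these overlaps were 9, 6, 7, 2 and 48, and 2 for hippocampus at 24 h and cortex at 6 h. With a peak in at least 2 LPS or both saline libraries, 1 region was higher in hippocampus at 6 h, and in cortex 106 were higher and 101 lower at 6 h, 26 lower at 12 h and 350 lower at 24 h. In that setting 1 list passed, synaptic genes among regions lower in hippocampus at 12 h (odds ratio 0.142, Fisher's exact test, adjusted p = 0.0292).

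Gene ends among regions higher in hippocampus at 24 h no longer passed at 5 kb (odds ratio 0.560, Fisher's exact test, adjusted p = 0.0962) or against windows in every library (0.507, adjusted p = 0.640), nor did regions lower in cortex at 6 h against windows in every library (0.252, adjusted p = 0.0704).

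With the 50000 strongest peaks 14784 windows went towards hippocampus and 15119 towards cortex, and 6429 of these 29903 were also called with all peaks in the same direction. Ntm (3) and Hecw2 (1) turned towards hippocampus. List splits no longer passed for endothelial (odds ratio 2.43), excitatory (0.691), inhibitory (1.72), hippocampal (1.38), cortical layer (0.756), cholinergic (0.584), clock (0.511) and synaptic genes (0.756). Interferon (0.767), microglia (0.629) and astrocyte lists (0.842) turned, and oligodendrocyte markers passed (0.222, Fisher's exact test, adjusted p = 0.0148). Without the 2 genes that leaned furthest, the 8 lists no longer passed, at 1.41, 0.808, 1.12, 1.11, 0.762, 0.975, 0.596 and 0.845 in that order, and acute inflammatory (0.856), glucocorticoid (1.29), immediate early (1.22), microglia (0.983), astrocyte (0.818) and oligodendrocyte lists (1.11) turned. With gene bodies or 10 kb around them, endothelial (1.51) and cholinergic genes (0.637) no longer passed and glucocorticoid (1.05) and immediate early genes (1.11) turned. The replicate block over animals called 41780 and 26637 windows, and all 68417 were also called without it in the same direction. It was not run for lists or differential regions. Leaving out each animal gave 52114 to 56142 and 33917 to 37035 windows, and without the animal whose cortex library stood apart it was 54080 and 35095.

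For windows gained with LPS, the share of splits with as many fell to 0.0182 in hippocampus and 0.0364 in cortex with the 50000 strongest peaks. Against the median of other splits, that setting turned hippocampus gained (0.2) and lost windows at 6 h (0.9), cortex gained at 6 h (0.3) and cortex lost at 24 h (0.2). Without the 3 animals with replicate number 1, hippocampus lost at 12 h, hippocampus gained at 24 h and cortex lost at 12 h turned (each 0.667). Leaving out 1 library each, these shares ranged from 0.25 to 0.667 for cortex gained at 12 h, 0.5 to 0.833 for cortex and hippocampus gained at 6 h, 0.0444 to 0.2 for cortex gained over all times, 0.25 to 0.75 for hippocampus gained at 24 h, cortex lost at 6 and 12 h and hippocampus lost at 12 h, 0.25 to 0.833 for cortex lost at 24 h, and 0.25 to 1 for hippocampus lost at 6 h.

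The tissue difference in intervals was 8882 (exact sign-flip p = 0.310) and that in the percentage near gene ends -0.631 (exact p = 0.0654) at a -log10 q of 5 or more, where the percentage near gene ends after LPS in hippocampus turned (0.355). With no replicate block the interval difference had a permutation p of 0.0465. Leaving out 1 animal each gave 16248 to 25766 intervals and 3.40 to 6.21 Mb between tissues, the latter without 6 h replicate 4 (exact p = 0.0293). Leaving out 1 library each, LPS minus saline ranged in hippocampus from -48770 to 7611 intervals, -13.6 to 10.9 Mb and -0.400 to 0.346 percentage points near gene ends, and in cortex from -23246 to 22602 intervals, -11.1 to 9.03 Mb and -0.776 to 0.263 points, and each turned sign without 1 saline library (replicate 2, or replicate 3 for gene ends), some also without an LPS library. Jaccard differences with the 50000 strongest peaks passed after adjustment for animals across tissues (0.00363, permutation p = 0.00694, adjusted 0.0174) and for groups in frontal cortex (0.0172, permutation p = 0.00684, adjusted 0.0174). That for groups in hippocampus (0.0163, permutation p = 0.0379, adjusted 0.0632) did not. Depth, which these files do not give, limits which weak peaks were found in each library.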

Other observations

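The striatal gene list, and the tests of a cell class changing with time, of a response shared by the 3 animals at 6 h and of a response to LPS among the lower regions, were chosen only after the result was seen. Striatal neuron markers had 31 windows among the regions higher in frontal cortex at 24 h, where 8.42 were expected, at 21 of 27 genes. Rarb, a retinoic acid receptor gene, had 5 such windows and Adcy5 had 3. The dopamine receptor genes Drd1 and Drd2, the adenosine receptor gene Adora2a and the opioid peptide genes Pdyn and Penk had 1 each, and Ppp1r1b, Tac1 and Scn4b had 0. The list was written after windows at Dlx6 and Pde10a had been seen among these regions. Both were left out of it, but Penk had also been seen, as a leading region. Of the 27 genes, 1 is also in a list fixed beforehand, and how many are expressed in cortex was not measured here.

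Several single regions recurred, chosen here after their values were seen. In the authors' deposited table an intron of Pax5, a B cell transcription factor gene, and a site 85995 bp from Ptpn1, a phosphatase gene, were each lower in 5 comparisons. In the authors' deposited table introns of Sgk3, Acsbg2 and Bcl2, an inhibitor of apoptosis, were each lower in 4. All comparisons of a tissue share its 2 saline libraries, and the tissues share the 2 saline animals.

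The regions higher in frontal cortex at 24 h were over-represented near striatal markers (odds ratio 3.86, 95% interval 2.68 to 5.54, unadjusted Fisher's exact p = 1.06e-09). That list was written after some of these regions had been seen, and windows of 1 gene are not independent, so this p decides little. Striatal tissue in some cortex pieces is only a candidate explanation. Whether more peaks in the 24 h libraries account for the pattern stays open: the share with a peak exceeded that of matched windows by 22.1 percentage points, which was to count against it, but the regions were chosen on these libraries and an excess was bound to appear. A change in a cell class with time after LPS also stays open, as replicate 1 at 6 h exceeded the other 6 h libraries by 33.9 percentage points, which is 1 library. A dissection difference and a late response to LPS cannot be told apart, since all 3 pieces at 24 h are of 1 group. Nor can an effect of collection time, since saline was collected at 6 h only.

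The regions higher in frontal cortex at 6 h may rest on replicate 1. Replicates 3 and 4 lay 1.24 percentage points above saline in the share with a peak, and 4.87 relative to each library's share of all windows present in 2 or more cortex libraries, which argues against a response shared by the 3 animals. Windows at these regions overlapped annotated pseudogenes in 7.45% of cases, against 0.618% of other windows (odds ratio 12.95, 95% interval 7.18 to 23.4), consistent with sequence that has copies elsewhere. Whether reads of repeated sequence were placed differently in this library stays open, as its 290 strong windows found in no other library were 2.82 times the 103 of the next, between the bounds of 2 and 5 set beforehand.

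Regions lower after LPS in frontal cortex may mark 1 saline animal. In hippocampus, saline replicate 2 had a peak in 85.7 to 91.1% of cases for the 3 sets of lower regions, which overlap each other and fell on 673 distinct windows. At the 73.3% of these windows that had a peak in at least 2 hippocampus libraries, the share was 97.4% against 82.3% at matched windows. The excess was 15.1 percentage points, where the other hippocampus libraries lay between -6.62 and 6.39. It was to count against a larger number of peaks in this animal's libraries. But the regions were chosen partly on its cortex library, and windows were matched only on the number of other hippocampus libraries with a peak. Whether a larger number of peaks is the cause therefore stays open. The libraries of this animal held the most windows found in no other library, 13821 in hippocampus and 10283 in cortex. A response to LPS shared by the animals stays open: saline replicate 3 differed from the mean of the 9 LPS libraries of cortex by -0.0582 percentage points, but it is 1 library, and relative to each library's share of all windows present in 2 or more cortex libraries the difference was 6.76. That relative value was -1.91 points in saline replicate 3 and -14.4, -25.3 and -18.2 in the 24 h libraries for regions lower at 24 h, but -3.68 against 1.76, -16.7 and -6.69 in the 6 h libraries for those lower at 6 h, and -7.49 against -36.5, -13.2 and 1.51 in the 12 h libraries for those lower at 12 h.

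For the windows between hippocampus and frontal cortex, 1 of 100 splits of the 22 libraries, the real one, gave as many called windows, 99757. The highest of the others gave 0. This argues against chance, though 1 of 100 is the smallest share that the test allows. The splits do not part tissue from other differences between the libraries of the tissues, such as read depth. Of the other splits 49 exchanged tissues within animals, as the real one parts them, and 50 were drawn freely.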
